A study of Homo sapiens with 8 samples.

How the data were processed

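RNA from HCT116 colon cancer cells was amplified to biotin-labelled cRNA and hybridized to Illumina expression chips. The 8 arrays form 4 groups of 2 by genotype (p53-/- or p53+/+) and treatment (none, or P2), taken from the sample titles. P2 was used at 25 µM, a dose that the titles do not give. The submitters' processing notes name GenomeStudio, without its version or role. The deposited non-normalized table holds an intensity per probe and array, the mean over beads, without background subtraction or scaling between arrays. Beside it the deposited table gives a detection p-value per probe and array against negative control probes. The authors also deposited log2 values, which were checked to equal the quantile-normalized log2 intensities, with a largest difference of 5.0e-09. Of 24526 probes, 21834 carried 1 gene symbol in the annotation, 2692 carried none and 0 carried several.

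The values reported here start from the non-normalized intensities. Background was corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values and an offset of 16, followed by log2 and quantile normalization between arrays. Probes with a detection p under 0.05 on at least 2 arrays were tested, which kept 14574 probes (10932 genes, 1756 with over 1 tested probe) and left out 9952. A linear model with 1 mean per group was fitted to all 8 arrays with limma, since groups of 2 share 1 estimate of the spread (4 residual and 5.15 prior degrees of freedom). The 5 contrasts were P2 minus untreated in each genotype, the difference between these effects, and p53+/+ minus p53-/- in untreated and in treated cells. Moderated two-sided tests were adjusted by Benjamini-Hochberg over all tested probes within each contrast, with a threshold of 0.05. Where a gene was detected on no array of a group, its fold is given as "at least", computed against the lowest log2 value among detected probes, while log2 changes are as fitted.

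The tests, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The 32 lists were p53 targets, E2F and DNA replication, mitosis, histone genes, ATF4 and integrated stress response, endoplasmic reticulum chaperones, heat shock response, NRF2 and oxidative stress, metallothioneins and zinc, hypoxia, glycolysis, oxidative phosphorylation, cholesterol and sterol synthesis, fatty acid synthesis, aryl hydrocarbon receptor, NF-kB and inflammatory cytokines, interferon response, immediate early genes, Wnt and beta-catenin targets, MYC and ribosome biogenesis, ribosomal proteins, apoptosis regulators, autophagy and lysosome, proteasome, DNA repair, iron handling, TGF-beta targets, epithelial and colon differentiation, mesenchymal and cytoskeletal genes, and markers of fibroblasts, leukocytes, and endothelial and erythroid cells. Of 867 members, 659 were measured. Lists with at least 5 measured members (30 of 32) were tested with limma's camera at a preset correlation of 0.01, 1 probe per gene (the brightest tested one), adjusted over lists within each contrast. Member counts are given over all probes and adjusted over the list alone.

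Named genes were CDKN1A and MDM2, the 10 largest rises and 10 largest falls of each P2 contrast, and the largest differences between untreated genotypes. These had an adjusted p under 0.05 and arrays that did not overlap between groups, with 1 probe per gene in each set of 10 and without probes lacking a symbol. For the difference in response, the 3 smallest p in each direction were named. From each list that passed or had at least 3 called members, up to 4 called members with the largest change were named. The targeted gene is not analysed here.

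Each result was recomputed without background correction, with an offset of 50, with median scaling or cyclic loess, from the authors' log2 values, without the filter, with a detection p under 0.01 on all 8 arrays, with a variance trend and robust moderation, with array weights, on the groups of the comparison alone, with the replicate number as a block, with a minimum change of 1.5-fold and without each array in turn. The lists were also tested with an estimated correlation, with fry, and with the mean of a gene's probes. Alternatives and the lists of YAP and TEAD targets and antigen presentation genes added after the data were seen are named as such in the closing section. Splits of the arrays into other groups were not counted, since each group holds 2 arrays. The pipeline was tested on simulated data, and the plots were drawn with matplotlib 3.10.9 in Python 3.11.15.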

Results

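Total RNA of HCT116 cells, an established human colon cancer line, was measured on Illumina expression chips in 4 groups of 2 arrays. The groups were p53-/- and p53+/+ cells, each untreated or treated with the small molecule P2 at 25 µM. The sample titles call the controls untreated and name no solvent control. Each P2 effect given here may thus hold an effect of solvent or handling. The extraction notes mention frozen tissue, although the samples are described as a cell line, and this was not resolved. The labels give no treatment time and no chip positions, and no genome build is named, so genes are given by symbol and probe without coordinates. Each array held 24526 probes, with a median intensity of 52.2 to 69.1. Between 12775 probes (52.1%, p53-/- untreated replicate 1) and 13998 probes (57.1%, p53-/- P2 replicate 1) were detected. Across the 14574 tested probes, the 2 replicates correlated with r = 0.989 in untreated p53-/- cells, 0.995 in P2-treated p53-/- cells, 0.995 in untreated p53+/+ cells and 0.995 in P2-treated p53+/+ cells. The first principal component held 61.4% of the variance and placed the 4 untreated arrays between -45.1 and -8.32 and the 4 treated arrays between 18.5 and 26.5. On p53-/- untreated replicate 1, 215 probes of 182 genes were at least 1 log2 lower than on replicate 2 and 0 were at least 1 log2 higher. In each of the other groups, 0 to 6 probes were lower and 0 to 4 higher by that much on replicate 1. The labels do not say whether the 2 arrays of a group come from separate cultures, so the p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision.

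The first comparison asked which genes P2 changed in cells without p53. PROM1 (probe ILMN_1786720), a cholesterol-binding membrane glycoprotein used as a stem cell marker, rose by 5.10 ± 0.10 log2 (SE, n = 2 arrays per group), at least 26.3-fold, with an adjusted p of 2.0e-08. NRIP1 (ILMN_1718629), a corepressor of nuclear receptors, rose by 4.13 ± 0.13 log2 (17.6-fold, adjusted p = 5.0e-07), and EIF4E3, a cap-binding protein, by 3.50 ± 0.17 (11.3-fold, adjusted p = 5.0e-06). TM4SF18, a membrane protein, fell by 4.41 ± 0.11 log2 (21.2-fold, adjusted p = 1.2e-07), and ZBED2, a zinc finger transcription factor, fell by 4.19 ± 0.11 (18.3-fold, adjusted p = 1.2e-07). The other genes among the 10 largest falls included the Notch ligand-like gene DNER, which fell by 3.03 (8.16-fold), the ERBB ligand NRG1, which fell by 2.79 (6.90-fold), the growth factor gene FGF9, which fell by 2.35, and the Wnt ligand genes WNT16, which fell by 2.26, and WNT3A, which fell by 2.22 log2. The neuronal glucose transporter gene SLC2A3 fell by 2.26, NAV3 fell by 2.20 and GLIS3 fell by 2.15 (at least 4.24-fold).

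The remaining 7 of the 10 largest rises came from probes that were low on p53-/- untreated replicate 1. They were TRNP1 (3.99 ± 0.34 log2), TNFRSF6B (3.76 ± 0.56), CDC14B (3.65 ± 0.54), ALYREF (3.52 ± 0.84), CD151 (3.38 ± 0.61), ALDOA (3.14 ± 0.81) and DUSP4 (3.13 ± 0.53). Where such a gene had other tested probes, their median P2 effect was -0.44 log2 for CDC14B, 0.37 for CD151 and 0.028 for ALDOA, an enzyme of glycolysis. Of the 2 other ALDOA probes 1 lay near background on each array (4.72 to 5.04), where a change would be hard to see. Set against untreated replicate 2 alone, a check chosen after the data were seen, the 7 probes differed by 1.45 (ALDOA) to 3.31 log2 (TRNP1) in treated p53-/- cells. On replicate 2 the 7 probes were themselves 1.12 (TNFRSF6B) to 1.49 log2 (CDC14B) lower than in untreated p53+/+ cells. Whether replicate 2 shares the deviation stays open, which limits each value set against it. Without p53-/- P2 replicate 1 the calls of ALYREF and ALDOA were lost (adjusted p = 0.0991 and 0.124), as they were without p53-/- P2 replicate 2 (0.0615 and 0.0765), without the filter on dim probes (0.0584 and 0.0751), with a variance trend and robust moderation (0.114 and 0.136) and with only these 2 groups fitted (0.0562 and 0.0678). The call of CD151 was lost with a variance trend and robust moderation (0.0590). The 215 low probes had a median P2 effect of 1.33 log2 in p53-/- cells, a value that their choice raises by construction, 0.64 against untreated replicate 2 alone, and 0.24 log2 in p53+/+ cells, and 147 of them were among the rises in p53-/- cells.

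**Figure D1:**
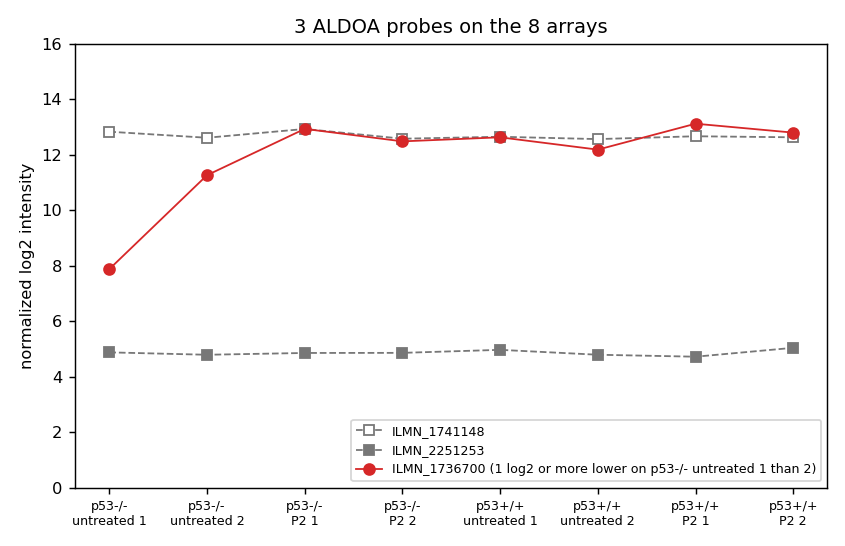
Normalized log2 intensity (y axis) of the 3 ALDOA probes on each of the 8 arrays (x axis), 1 point per array. The probe in red lay at 7.88 on p53-/- untreated replicate 1 and 11.27 on replicate 2, against 12.2 to 13.1 on the other 6 arrays, while the 2 other probes stayed between 12.6 and 12.9 and between 4.72 and 5.04.

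In all, limma called 3706 of 14574 probes at an adjusted p under 0.05 in p53-/- cells, 1722 higher (1381 genes) and 1984 lower (1710 genes), of which 525 and 168 changed by over 2-fold. The count was 2173 without p53-/- untreated replicate 1 (2036 of them shared with the full set), 1536 without p53-/- P2 replicate 1 and 2123 without p53-/- P2 replicate 2. It was 2400 when only these 2 groups were fitted and 2014 with a minimum change of 1.5-fold.

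Of 30 gene lists fixed before the data were examined, 5 rose under P2 in p53-/- cells by the camera test. Among 38 measured p53 targets, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with a median change of 0.24 log2 and a list adjusted p of 0.000118. The stress cytokine gene GDF15 rose by 2.49 ± 0.13 log2, and CDKN1A (ILMN_1784602), the cell cycle inhibitor p21, by 1.73 ± 0.11 log2 (3.32-fold, adjusted p = 2.6e-05), while PLK2 fell by 1.26 ± 0.14. Interferon response genes rose in 14 and fell in 3 of 24 measured members (15 and 3 adjusted over the list alone), with a median of 0.40 log2 and a list adjusted p of 0.000153. BST2, which tethers virus particles, rose by 1.22 log2 and IFIT2 by 0.98, while the exonuclease gene ISG20 fell by 0.71. Cholesterol and sterol synthesis genes rose in 7 of 18 members and fell in 0 (8 and 0 adjusted over the list alone; median 0.32 log2, list adjusted p = 0.000622). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose by 1.07, the squalene epoxidase gene SQLE by 0.92 and CYP51A1 by 0.88 log2. With an estimated correlation between genes, the adjusted p was 0.263 for the p53 targets, 0.267 for the interferon genes and 0.269 for the cholesterol genes.

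Epithelial and colon differentiation genes rose in 7 of 13 measured members and fell in 0 (7 and 0 adjusted over the list alone; median 0.46 log2, list adjusted p = 0.00916) in p53-/- cells. The carbonic anhydrase gene CA2 rose by 1.34 log2 and the tight junction genes CLDN7 and CLDN3 by 1.20 and 0.87. With the mean of the low probes as a covariate, chosen after the data were seen, CLDN7 was at 0.44 log2 and not called (adjusted p = 0.284). The list member KRT18, which rose by 1.65 log2, was measured by a probe that was low on p53-/- untreated replicate 1. Its call was lost without either P2-treated p53-/- array or any 1 of the p53+/+ arrays. It was also lost with cyclic loess (adjusted p = 0.0504), no filter (0.106), a variance trend and robust moderation (0.165) or only these groups fitted (0.0961). Fatty acid synthesis genes rose in 4 of 11 members and fell in 0 (5 and 0 adjusted over the list alone; median 0.27 log2, list adjusted p = 0.0435), among them the desaturase gene FADS1 by 0.76 log2. The adjusted p with an estimated correlation was 0.267 for the epithelial and 0.634 for the fatty acid list. The epithelial list was not called without the filter on dim probes (adjusted p = 0.113), nor with the mean of the low probes as a covariate. The fatty acid list was not called without p53-/- untreated replicate 2 (adjusted p = 0.1004), p53-/- P2 replicate 2 (0.111), p53+/+ untreated replicate 1 (0.0515) or p53+/+ untreated replicate 2 (0.0512), nor with median scaling (0.413), cyclic loess (0.0814) or the stricter detection filter (0.0577).

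Some lists held called members in p53-/- cells without passing as lists. Wnt and beta-catenin targets fell in 5 of 16 members and rose in 0 (5 and 1 adjusted over the list alone; median -0.21 log2, list adjusted p = 0.0843). The negative feedback genes of this pathway AXIN2 and NKD1 fell by 1.24 and by 1.22, the Notch ligand gene JAG1 fell by 1.06 and the protease gene PRSS23 fell by 1.01 log2. Immediate early genes rose in 4 and fell in 9 of 29 members (5 and 10 adjusted over the list alone; median -0.047 log2, list adjusted p = 0.373), with DUSP4, measured by a low probe, among the rises. The kinase gene SGK1 fell by 2.01, the matricellular protein gene CCN2 fell by 1.63 and the transcription factor gene KLF4 fell by 0.86 log2. Mitosis genes fell in 8 of 42 members and rose in 0 (8 and 0 adjusted over the list alone; median -0.14 log2, list adjusted p = 0.208), among them the kinetochore gene CENPF, which fell by 0.78. For each of these 3 lists the adjusted p was 0.634 with an estimated correlation, and with median scaling the Wnt list passed (adjusted p = 0.0448).

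The second comparison asked which genes P2 changed in cells with p53. PROM1 rose by 4.65 log2 (at least 21.5-fold) and NRIP1 by 3.97 (15.7-fold). EHF, an epithelial transcription factor of the ETS family, rose by 3.32 ± 0.17 log2 (adjusted p = 8.6e-06), and the inflammatory caspase gene CASP4 by 3.26 ± 0.13 (9.61-fold), whose other tested probe changed by 0.73. EIF4E3 rose by 3.17 log2, the iron-scavenging lipocalin gene LCN2 by 3.15 (at least 7.97-fold), the formin gene DIAPH2 by 2.68 (at least 5.19-fold), GDF15 by 2.58 ± 0.13 (5.98-fold), DPYSL3 by 2.52 and the calcium-binding protein gene S100A4 by 2.39. TM4SF18 fell by 4.71 ± 0.11 log2 (at least 25.6-fold, adjusted p = 6.4e-08), ZBED2 fell by 3.92, DNER fell by 3.11, NRG1 fell by 2.99, FGF9 fell by 2.76 and SLC2A3 fell by 2.25. The other genes among the 10 largest falls were GLIS3, which fell by 2.17 (at least 3.78-fold), the adhesion gene NECTIN3, which fell by 2.15, SGK1, which fell by 2.04, and the growth factor gene BMP4, which fell by 1.99 log2 (other probe -1.64). In p53-/- cells the same BMP4 probe fell by 1.83 log2, while its other probe, which was low on untreated replicate 1 (4.71 against 6.79 on replicate 2), changed by 0.34, or by -0.70 against replicate 2 alone.

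**Figure D2:**
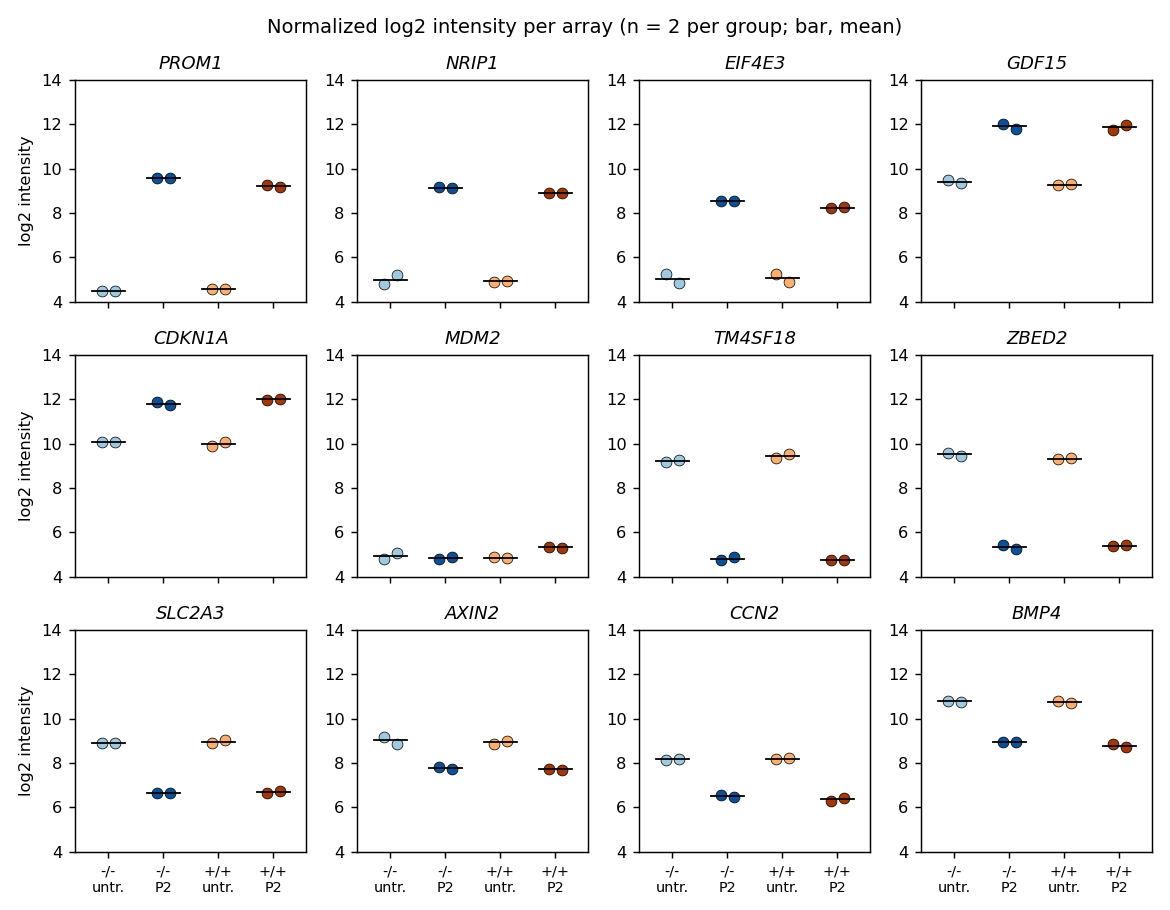
Normalized log2 intensity (y axis) of 12 genes on each array (dots, n = 2 per group; bars, group means), by genotype and treatment (x axis). PROM1 means were 4.48 and 9.58 in untreated and treated p53-/- cells and 4.56 and 9.20 in p53+/+ cells, and the 2 TM4SF18 arrays of each treated group lay below the 2 of each untreated group.

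In p53+/+ cells limma called 1749 probes, 832 higher (695 genes) and 917 lower (801 genes), of which 140 and 101 changed by over 2-fold. The count was 584 without p53+/+ untreated replicate 1, 675 without p53+/+ untreated replicate 2, 587 without p53+/+ P2 replicate 1 and 654 without p53+/+ P2 replicate 2. It was 1013 with median scaling, of which 296 were higher and 717 lower, and 927 with a minimum change of 1.5-fold.

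By the camera test 8 lists passed in p53+/+ cells. Interferon response genes rose in 15 and fell in 1 of 24 members (17 and 1 adjusted over the list alone; median 0.49 log2, list adjusted p = 3.4e-09). BST2 rose by 1.59 log2 (at least 2.83-fold), IFIT2 by 1.23 and the transcription factor gene IRF1 by 1.07. Among the p53 targets 11 rose and 1 fell of 38 (12 and 1 adjusted over the list alone; median 0.25 log2, list adjusted p = 4.7e-06). CDKN1A rose by 2.01 ± 0.11 log2 (4.04-fold, adjusted p = 8.8e-06) and TP53INP1 by 1.24 ± 0.12, while PLK2 fell by 1.75 ± 0.14. Cholesterol and sterol synthesis genes rose in 6 of 18 and fell in 0 (6 and 0 adjusted over the list alone; median 0.31 log2, list adjusted p = 2.5e-05), with INSIG1 at 1.04 and SQLE at 0.78 log2, the latter not called with median scaling (adjusted p = 0.0727). Fatty acid synthesis genes rose in 5 of 11 and fell in 0 (6 and 1 adjusted over the list alone; median 0.37 log2, list adjusted p = 0.00285), with the regulator gene SREBF1 at 0.80 log2, not called with median scaling (adjusted p = 0.0610). Epithelial genes rose in 3 of 13 and fell in 0 (3 and 0 adjusted over the list alone; median 0.23 log2, list adjusted p = 0.00279), with CLDN3 at 1.26 and CA2 at 1.06 log2. With an estimated correlation the adjusted p was 0.0964 for the interferon and p53 lists, 0.162 for the cholesterol and epithelial lists and 0.507 for the fatty acid list.

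The 3 other lists passed downward in p53+/+ cells. Mitosis genes fell in 4 of 42 members and rose in 0 (1 and 0 adjusted over the list alone; median -0.19 log2, list adjusted p = 0.00279). The cyclin gene CCNB1 fell by 0.59 log2, a call that was lost without p53+/+ untreated replicate 2 (adjusted p = 0.0919), p53+/+ P2 replicate 1 (0.0939) or p53+/+ P2 replicate 2 (0.0542). Wnt and beta-catenin targets fell in 6 of 16 and rose in 0 (7 and 1 adjusted over the list alone; median -0.34 log2, list adjusted p = 0.0137). AXIN2 fell by 1.21, JAG1 fell by 1.12 and NKD1 fell by 0.82 log2. The Wnt list was not called without p53+/+ P2 replicate 1 (adjusted p = 0.105) or with the stricter detection filter (0.246). Immediate early genes fell in 7 of 29 and rose in 1 (7 and 2 adjusted over the list alone; median -0.17 log2, list adjusted p = 0.0140), with CCN2, which fell by 1.84, KLF4, which fell by 1.13, and the phosphatase gene DUSP6, which fell by 1.12. The adjusted p with an estimated correlation was 0.229 for mitosis, 0.576 for Wnt and 0.233 for the immediate early genes, and none of the 5 list calls in p53-/- cells and 8 in p53+/+ cells holds with it.

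**Figure D3:**
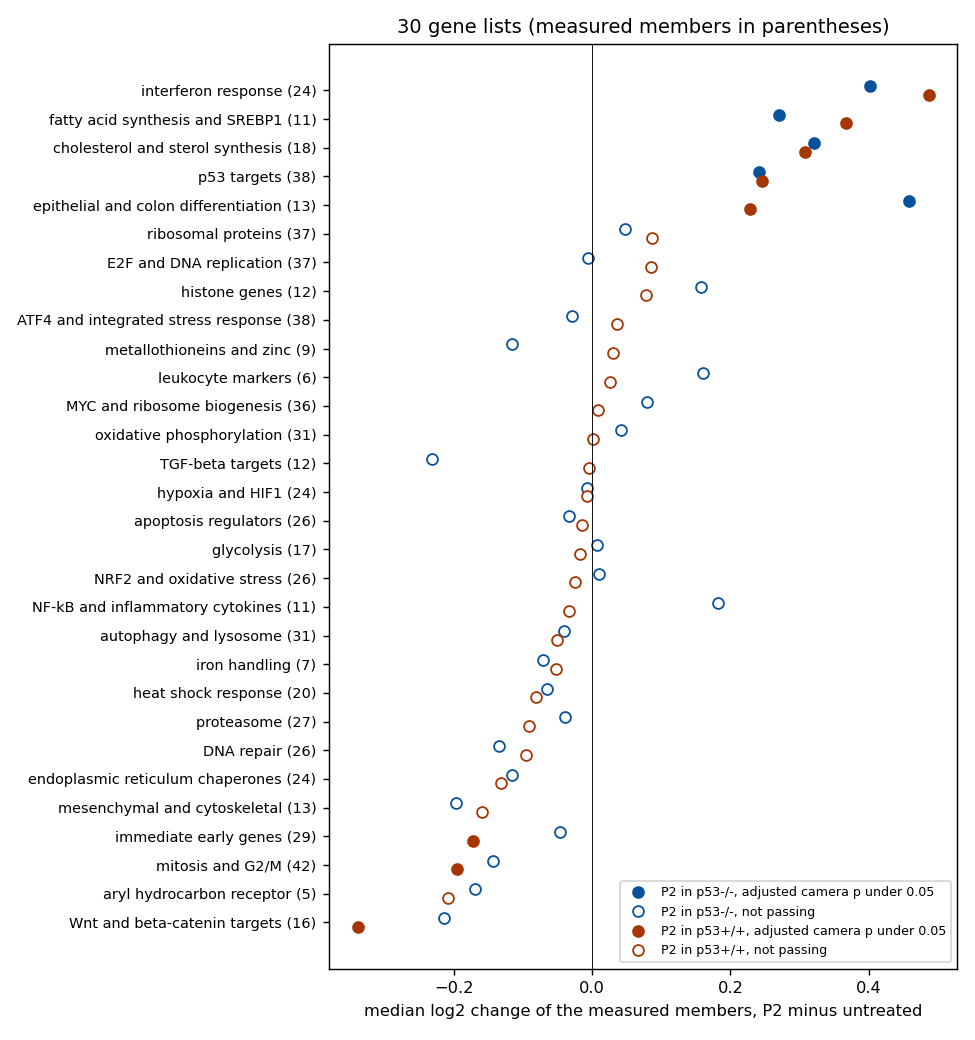
Median log2 change under P2 (x axis) of the measured members of 30 gene lists (y axis), with p53-/- cells in blue and p53+/+ cells in orange and filled points for lists with an adjusted camera p under 0.05. The interferon medians were 0.40 and 0.49 log2, and the Wnt medians were -0.21 and -0.34 log2.

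The third comparison asked whether the response to P2 differed between the genotypes. The P2 effects of both genotypes correlated across the 14574 probes with r = 0.62 and rho = 0.55, where genes are not independent replicates. Of the probes called higher, 459 were shared, against 98.3 for independent calls, and of those called lower 678 were shared, against 125. The effect had the same sign in p53-/- cells for 88.9% of the rises and 96.5% of the falls called in p53+/+ cells, and 9 probes were called in opposite directions. For CDKN1A the P2 effect in p53+/+ minus that in p53-/- cells was 0.28 ± 0.15 log2 (adjusted p = 0.402). For MDM2, the ubiquitin ligase of p53, P2 changed the level by -0.074 ± 0.12 log2 in p53-/- cells (adjusted p = 0.677) and 0.46 ± 0.12 in p53+/+ cells (adjusted p = 0.0348), with a difference of 0.53 ± 0.16 (adjusted p = 0.174). The MDM2 call was lost without any 1 of the 4 p53+/+ arrays (adjusted p 0.130 to 0.152) or of the 2 P2-treated p53-/- arrays (0.0551 and 0.0566). It was also lost with no background correction, an offset of 50, median scaling, the authors' values or a minimum change of 1.5-fold. The targeted gene itself is not analysed here.

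**Figure D4:**
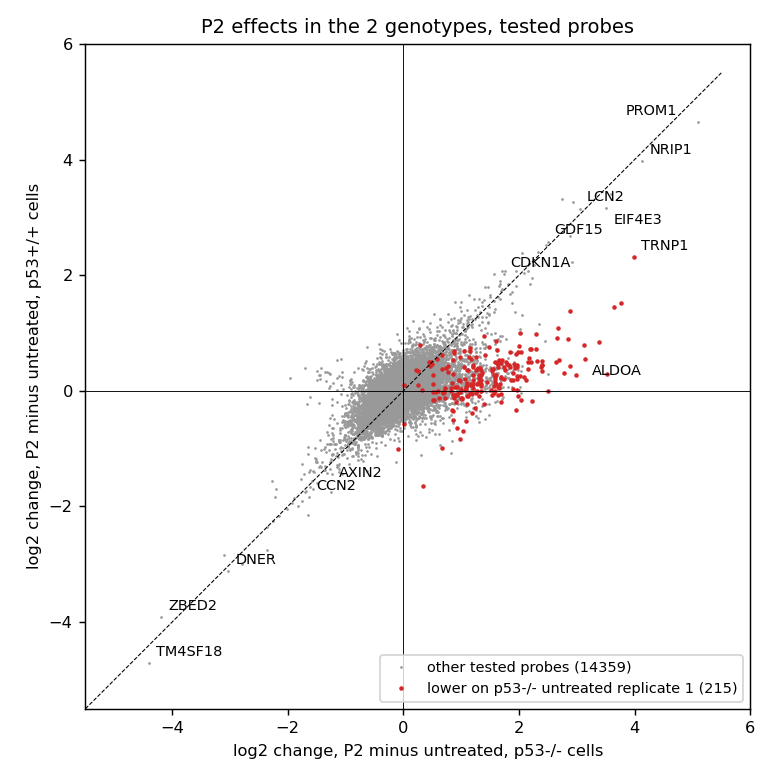
Log2 change under P2 of each tested probe in p53-/- cells (x axis) and in p53+/+ cells (y axis), with the line of equal change dashed. The 215 probes that were at least 1 log2 lower on p53-/- untreated replicate 1 than on replicate 2 are in red, with median changes of 1.33 (0.64 against replicate 2 alone) and 0.24 log2.

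Limma called 0 probes for the difference in response, with 2383 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0739. The probes with the smallest p, none of them passing, were LCOR (-2.07 ± 0.23 log2), H4C3 (-1.65 ± 0.20) and DFFA (-1.37 ± 0.16, other probe 0.29) in 1 direction, and RTL8A (1.33 ± 0.17), JAG2 (1.16 ± 0.17, other probe 0.12) and SYNGR1 (1.07 ± 0.15, other probes 0.18) in the other. No list passed by camera, with a smallest adjusted p of 0.395, while with median scaling the histone list passed downward (median -0.11 log2, adjusted p = 0.00905), and the difference for the p53 target list was 0.065 log2 in the median and -0.019 in the mean (adjusted p = 0.941). Without p53-/- untreated replicate 2 the count was 973, without p53+/+ P2 replicate 1 it was 80, and without any 1 of the other arrays it was 0. Other settings gave 73 (no background correction, or the authors' values), 466 (median scaling), 87 (stricter detection filter) and 182 (variance trend and robust), and the other settings fixed beforehand gave 0.

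The fourth comparison, of untreated p53+/+ with untreated p53-/- cells, addressed the genotype difference before treatment. The corepressor gene LCOR was 1.28 ± 0.16 log2 higher in p53+/+ cells (2.43-fold, n = 2 arrays per group, adjusted p = 0.0443), the histone gene H4C3 1.25 ± 0.14 higher (adjusted p = 0.0338), the apoptotic nuclease inhibitor gene DFFA 1.17 ± 0.11 higher (at least 1.93-fold, adjusted p = 0.0338) and the transcription factor gene USF1 1.15 ± 0.13 higher (adjusted p = 0.0338). The lysosomal protease gene CTSB was 0.95 log2 higher, and FSD1, detected on neither untreated p53-/- array, at least 1.36-fold higher. In p53+/+ cells the level of the adhesion gene BCAM differed by -1.41 ± 0.16 log2 (adjusted p = 0.0338), that of ATN1 by -1.20, that of RTL8A by -1.01 and that of AP1B1 by -0.95. Other tested probes gave -0.25 log2 for DFFA, 0.47 for USF1, 0.64 for FSD1, 0.29 for BCAM, 0.040 for AP1B1 and 0.045 for ATN1, whose other probe was low on p53-/- untreated replicate 1 and differed by -0.56 against replicate 2 alone. CDKN1A differed by -0.081 ± 0.11 log2 (adjusted p = 0.735) and MDM2 by -0.063 (adjusted p = 0.815). The 38 p53 targets had a median difference of -0.069 log2 and a mean of 0.0089 (list adjusted p = 0.987). The count of 10 probes, 6 higher and 4 lower, with 2892 at an unadjusted p under 0.05, became 1319 without p53-/- untreated replicate 2, 72 without p53+/+ P2 replicate 1, 60 without p53+/+ P2 replicate 2, 6 without p53-/- untreated replicate 1 and 0 without any 1 of the 4 other arrays. It was 0 with cyclic loess, no filter, the 2 groups fitted alone or the replicate number as a block, and up to 621 (median scaling) with the others, and each of these 10 calls was lost in several settings.

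No list passed between the untreated genotypes by camera, where the smallest adjusted p was 0.0618, for the histone genes (median 0.093 log2, 1 of 12 members higher, 3 adjusted over the list alone) and the immediate early genes (median 0.061 log2, 0 of 29 members passing, 2 higher adjusted over the list alone). Each list holds 1 probe that was low on p53-/- untreated replicate 1, H2AX at 2.32 log2 (0.98 against replicate 2 alone) and DUSP4 at 2.40 (1.40), neither passing over all probes, and without the 215 low probes, an alternative chosen after the data were seen, the adjusted p was 0.141 for both lists. The histone list passed without p53-/- untreated replicate 2 (adjusted p = 0.00767), p53+/+ untreated replicate 1 (0.0199), p53+/+ P2 replicate 1 (0.0440) or p53+/+ P2 replicate 2 (0.0440). The immediate early gene list passed without p53+/+ P2 replicate 1 (adjusted p = 0.0440) or p53+/+ P2 replicate 2 (0.0440). With an offset of 50 both passed (adjusted p = 0.0494), and with the mean of a gene's probes both passed (0.0201 for histones and 0.0290 for immediate early genes) beside the apoptosis regulators (0.0113). With median scaling the histone list (1.0e-05) and the epithelial list (0.00937, up by camera with a median of -0.023 log2) passed.

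The fifth comparison set P2-treated p53+/+ against P2-treated p53-/- cells. CDKN1A was at 0.20 ± 0.11 log2 (adjusted p = 0.440) and MDM2 at 0.47 ± 0.12 (adjusted p = 0.175) in p53+/+ relative to p53-/- cells, and neither passed. The p53 target list had a median difference of -0.011 log2 (list adjusted p = 0.965) and the interferon list one of 0.12 (list adjusted p = 0.244). The mitosis list, at -0.12 log2, had the smallest list adjusted p, 0.187, and passed without the filter on dim probes (0.0229) and with median scaling (0.0285). The ribosomal protein list, at 0.034 log2 (list adjusted p = 0.965), passed with median scaling (0.0265) and with cyclic loess (0.0417). Limma called 0 probes, with 2011 at an unadjusted p under 0.05 and a smallest adjusted p of 0.170, and 0 with any 1 array left out. Other settings gave 2 (no background correction, or the authors' values), 3 (stricter detection filter) and 58 (variance trend and robust).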

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

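In the first weighed pattern each of the tests below, and in the second the 2 tests after the first, were chosen only after the result was seen.

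Results in this part have a P2 effect that differed between the genotypes by limma's interaction test adjusted over their list alone. Of 659 list members, 16 in 13 of 30 lists did so, and none of them passes over all probes. The values are the P2 effect in p53+/+ minus that in p53-/- cells. Without p53-/- untreated replicate 1 the 16 genes kept their sign, with a median size of 1.00 log2 against 1.05. They were chosen on the same arrays, most of which remain in this check, so it is a weak one. In 12 of the 16 the genotypes differed more in the untreated than in the treated arrays. Another tested probe existed for 1 of them, CYFIP2, and differed by 0.077 log2.

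Among the p53 targets the RNA-binding protein gene ZMAT3 differed by -1.53 log2 (P2 effects 1.77 in p53-/- and 0.24 in p53+/+ cells). CYFIP2 differed by 0.70 log2 (0.47 and 1.17). The histone gene H4C3 differed by -1.65 log2 (1.73 and 0.072). PPID, a cochaperone in the heat shock list, differed by 1.45 log2 (-1.67 and -0.23). TRIM16L in the oxidative stress list differed by 2.19 log2 (-1.96 and 0.23). The metal-responsive transcription factor gene MTF1 differed by -1.90 log2 (0.83 and -1.07). In respiratory complex I, NDUFC2 differed by 1.15 log2 (-0.64 and 0.51) and NDUFS1 by -1.07 (1.21, at least 2.08-fold, and 0.15). UTP20, needed for ribosome assembly, differed by 1.03 log2 (-0.91 and 0.12). In the autophagy and lysosome list UVRAG differed by -0.64 log2 (0.42 and -0.21) and the protease gene CTSB by -0.91 (0.98 and 0.071). The proteasome subunit gene PSMD11 differed by -0.90 log2 (0.61 and -0.29). BRIP1, a DNA repair helicase, differed by 1.73 log2 (-1.45 and 0.28). SMAD6, an inhibitor of BMP signalling, differed by 0.82 log2 (-0.64 and 0.18). SNAI1, a repressor of epithelial genes, differed by -0.72 log2 (0.22 and -0.50). The lysozyme gene LYZ in the leukocyte list differed by 1.04 log2 (-0.88 and 0.16).

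The first pattern is the 215 probes that were lower on p53-/- untreated replicate 1, with a median difference of -1.31 log2 between the replicates. Other tested probes, outside the set, existed for 117 of the 182 genes and fell by over 0.5 log2 in 9.40% of these. Where the other probes had room to fall, this goes against lower expression of the whole gene in that culture. Room to fall was not required of them, and dim ones could hardly fall, so the number of genes this covers is open. A probe that fell by at least 1 log2 was in the set and could not count as an other probe, which lowers this share by construction. The remaining genes had no tested probe outside the set, so they could not be tested. A loss of dim probes stays open, since among the 11558 probes with room to fall by 1 log2 the set's median level on the other arrays lay at percentile 44.7, neither among the dim probes nor above the middle. An effect on single probes may account for the pattern, as the 174 other probes of these genes had a median replicate difference of -0.039 log2. This value too leaves out the probes of the set by construction, and it may hold probes too dim to fall. At least part of the rise of the set under P2 in p53-/- cells may come from the untreated p53-/- arrays, as its median P2 effect was 0.24 log2 in p53+/+ cells against 1.33 in p53-/- cells. The choice of the set raises the 1.33 by construction, and against untreated replicate 2 alone the median was 0.64, so a P2 response of these probes that differs between the genotypes stays open. The set's median level on replicate 2 was 6.92, against 7.45 to 7.90 on the p53+/+ and the P2-treated arrays. The 0.64 may thus hold part of the same deviation. Whether the probes mark other transcripts of the same genes was not tested, since probe positions were not used here.

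The second pattern is that p53 targets had a median genotype difference of -0.069 log2 before treatment, with ZMAT3 at 1.33, and rose under P2 as a list in both genotypes, calls that were lost with an estimated correlation (adjusted p = 0.263 in p53-/- and 0.0964 in p53+/+ cells). Without p53-/- untreated replicate 1 the median difference of the list between untreated genotypes was -0.059 log2, so a difference hidden by that array did not appear. The test could hardly show one, since the large deviations of that array were toward lower values. These would widen and not hide a higher level in p53+/+ cells. From the values under P2, 2 accounts cannot be told apart. They are a wrong genotype label, or 1 genotype in both sets, and an induction by P2 that does not need p53. Either could give the median difference of -0.044 log2 between treated genotypes over the 17 targets called in either comparison. Either could also give the median P2 effect of 0.62 log2 in p53-/- cells over the 12 called in p53+/+ cells. An induction by P2 does not bear on untreated cells, where the list median was -0.069 log2. Such a value could follow from 1 genotype in both sets, while a plain swap of the labels would turn a difference around. How far these targets depend on p53 in untreated cells was not tested, so the untreated values leave the question open. MDM2 went the way the labels would have it, at -0.074 log2 under P2 in p53-/- and 0.46 in p53+/+ cells and 0.47 between treated genotypes. The 0.46 was not called in several settings, and neither the 0.47 nor the difference in response (0.53, adjusted p = 0.174) passed. By the difference in response adjusted over the list alone, ZMAT3 (-1.53 log2) and CYFIP2 (0.70) differed, and neither passed over all probes. In p53+/+ relative to p53-/- cells ZMAT3 was at 1.33 log2 before treatment and -0.20 after it. Its lower response thus goes with a higher untreated level in p53+/+ cells, so it is not evidence against the labels. CYFIP2 went with the labels, but its other tested probe differed by 0.077 log2. The 10 probes called between untreated genotypes do not settle the labels, since a difference between sets of arrays need not come from the genotype. Each of these calls was also lost in several settings. Other tested probes of DFFA, BCAM and AP1B1 did not share the difference, while those of USF1 and FSD1 went the same way. The targeted gene, whose own level would bear on this, is not analysed here.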

How the results depend on the processing

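With each array left out in turn, 70 of the 117 probes named for P2 in p53-/- cells (117 genes) and 48 of the 76 for P2 in p53+/+ cells (75 genes, S100A4 by 2 probes) kept their call each time, among them PROM1, NRIP1, EIF4E3, TM4SF18, ZBED2, DNER, GDF15, CDKN1A and CCN2. Under each alternative fixed beforehand 66 and 45 did, and for the untreated genotypes 0 of 10. The counts without 1 array were 1536 to 3878 for P2 in p53-/- cells, 584 to 2301 for P2 in p53+/+ cells, 0 to 973 for the difference in response, 0 to 1319 for the untreated genotypes, and 0 for the treated genotypes. Without p53-/- untreated replicate 1 the 2301 probes called in p53+/+ cells included each of the 1749. Lists passing between untreated genotypes numbered 0 to 2. The correlation of the P2 effects was 0.54 (without p53+/+ P2 replicate 1) to 0.66, and 0.56 without p53-/- untreated replicate 2. An arm left with 1 array was assumed to vary like the other groups.

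By setting, the counts that moved by over 1.5 times were as follows, and the cause was not tested unless stated. Without background correction, and equally from the authors' values, the difference in response gave 73 probes, the untreated genotypes 335 and the treated genotypes 2. An offset of 50 gave 6 probes and 2 lists for the untreated genotypes. Median scaling gave 1013 probes for P2 in p53+/+ cells, 466 and 1 list for the difference, 621 and 2 lists for the untreated and 2 lists for the treated genotypes. It moved the median change of all probes under P2 to -0.12 log2 in p53-/- and -0.11 in p53+/+ cells, from -0.042 and -0.0054. Cyclic loess gave 0 probes for the untreated genotypes and 1 list for the treated, and so did testing without the filter. A detection p under 0.01 on all 8 arrays gave 87, 187 and 3 probes for the difference, the untreated and the treated genotypes, and a variance trend with robust moderation gave 182, 255 and 58. Fitting only the groups compared, which leaves fewer degrees of freedom, gave 2400 for P2 in p53-/- cells and 0 for the untreated genotypes. A minimum change of 1.5-fold gave 2014 and 927 for P2 in p53-/- and p53+/+ cells by construction. The replicate number as a block gave 0 for the untreated genotypes. With an estimated correlation 0 lists passed for P2 in p53-/- or p53+/+ cells, with fry, which tests a list on its own, 15 and 13, and with the mean of a gene's probes 3 lists for the untreated genotypes. Array weights moved no count by that much, but the 2 arrays of each group got the same weight (0.74 for both untreated p53-/- arrays). This setting thus could not weigh p53-/- untreated replicate 1 below replicate 2. The autophagy list, up by camera in p53-/- cells (adjusted p = 0.985), went down by fry (median -0.040 log2, adjusted p = 0.0364). A chip block was not run, as no chip positions are given.

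Chosen after seeing the data, leaving out the 215 probes low on p53-/- untreated replicate 1 gave 123 for the difference and 300 for the untreated genotypes. Their mean as a covariate gave 567 for P2 in p53-/- cells, 517 of them shared with the full set, and 0 for the untreated genotypes. It turned the P2 effects of ALDOA, PSMC4 and KRT18 in p53-/- cells to -0.15, -0.19 and -0.28 log2, none of them called, which is by construction, since these probes belong to the set. Of the named calls it ended, 9 are of the set (median size 2.89 log2 before and 0.23 after). The 66 others had a median size of 0.66 with a median SE of 0.13 before and 0.48 with an SE of 0.20 after. Of them 14 were as large as before. A wider error thus took part, and the losses alone do not show that the effects came from that array. Some effects did shrink at a similar SE, such as RFC2 (0.79 to 0.15 log2, SE 0.19 both times) and BCL3 (0.64 to 0.020, SE 0.18 and 0.19). Without p53-/- untreated replicate 1 these were 0.46 and 0.32 log2, so part of these effects rests on that array. The epithelial list in p53-/- cells was lost too (adjusted p = 0.191). A block with the numbers of the 2 untreated p53-/- arrays crossed gave 296 and 791 for the difference and the untreated genotypes and ended the call of the fatty acid list in p53-/- cells (adjusted p = 0.0659). Deviations from the group mean correlated between arrays of the same number with r = 0.095 to 0.20 among the other groups. With untreated p53-/- cells r was -0.15 to -0.19. The labels do not say whether arrays of the same number belong together. Signal over background limits small changes in dim probes, since 52.1 to 57.1% of probes were detected on an array.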

Other observations

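The lists for YAP and TEAD targets and for antigen presentation were written after the values of CCN1, CCN2 and the interferon list were seen and before those of their members.

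None of the stress and metabolism lists or of the other lists in this and the next 2 paragraphs passed in either P2 comparison (adjusted camera p 0.132 to 0.985 in p53-/- and 0.201 to 0.928 in p53+/+ cells). ATF4 and integrated stress response genes rose in 8 and fell in 4 of 38 in p53-/- cells (9 and 5 adjusted over the list alone) and rose in 5 and fell in 1 in p53+/+ cells (5 and 1), with a median of -0.030 and a mean of 0.096 log2 in p53-/- cells. DDIT4, an inhibitor of mTOR signalling, rose by 1.33 and 1.36 log2, while DDIT3, the stress transcription factor CHOP, fell by 0.98 and by 0.84, the second call being lost without p53+/+ untreated replicate 2 (adjusted p = 0.0533) or p53+/+ P2 replicate 1 (0.0561). Hypoxia genes rose in 6 and fell in 7 of 24 (6 and 7 adjusted over the list alone) and rose in 2 and fell in 2 (4 and 3). The glucose transporter gene SLC2A1 fell by 1.72 and by 1.44 log2 and the peptide hormone gene ADM rose by 1.07 and 1.04. Oxidative stress genes of the NRF2 list rose in 4 and fell in 4 of 26 (4 and 4 adjusted over the list alone) and rose in 2 and fell in 1 (2 and 2), with AKR1C3 at 0.89 and 0.90 log2. Endoplasmic reticulum chaperones fell in 4 of 24 (4 adjusted over the list alone) and in 3 (3, with 1 rise), and heat shock genes in 3 of 20 (3) and 1 (1). Metallothionein and zinc genes fell in 1 of 9 (1 adjusted over the list alone) and in 1 (1, with 1 rise). Glycolysis genes fell in 3 of 17 and rose in 0 (1 and 0 adjusted over the list alone), then fell in 1 and rose in 1 (3 and 1). Oxidative phosphorylation genes rose in 2 and fell in 1 of 31 (1 and 0 adjusted over the list alone) and passed in 0 members in p53+/+ cells.

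Growth and genome lists were E2F and DNA replication, where 5 of 37 rose and 2 fell in p53-/- cells (5 and 2 adjusted over the list alone) and 2 rose in p53+/+ cells (0), and DNA repair, where 3 of 26 rose and 6 fell (3 and 6) and then 1 fell (0). Histone genes rose in 3 of 12 (3 adjusted over the list alone) and in 1 (1), and this list passed in p53-/- cells without p53-/- untreated replicate 2 (adjusted p = 0.0230), which leaves the array with the 215 low probes as the untreated arm, and with median scaling (0.00176). Of its rises H2AX was measured by such a probe, with 2.89 log2 against 1.54 over untreated replicate 2 alone. The H2AX call was lost without p53-/- P2 replicate 1 or p53-/- P2 replicate 2, and with a variance trend and robust moderation (adjusted p = 0.101). In the same way the rises in p53-/- cells include SLC3A2 in the ATF4, CTSD in the autophagy and PSMC4 in the proteasome list. MYC and ribosome biogenesis genes rose in 3 and fell in 1 of 36 (3 and 1 adjusted over the list alone) and rose in 1 and fell in 1 (1 and 1), with NOLC1, a nucleolar chaperone, at 1.24 log2 in p53-/- cells. Ribosomal protein genes rose in 4 and fell in 2 of 37 (2 and 1 adjusted over the list alone) and rose in 1 (0), and their list passed in p53-/- cells without p53-/- untreated replicate 2 (adjusted p = 0.0424), again with the low array alone. Proteasome genes rose in 2 and fell in 3 of 27 (2 and 3 adjusted over the list alone) and passed in 0 members in p53+/+ cells. Apoptosis regulators rose in 8 and fell in 3 of 26 (8 and 4 adjusted over the list alone) and rose in 1 and fell in 3 (1 and 3), and their list passed in p53-/- cells with the mean of a gene's probes (adjusted p = 0.0229). Autophagy and lysosome genes rose in 5 and fell in 7 of 31 (5 and 8 adjusted over the list alone) and rose in 1 and fell in 2 (3 and 2).

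Signalling and cell type lists included TGF-beta targets, where 1 of 12 rose and 5 fell in p53-/- cells (2 and 6 adjusted over the list alone) and 2 rose and 4 fell in p53+/+ cells (2 and 4). CCN2 fell by 1.63 and by 1.84 log2, the thrombospondin gene THBS1 fell by 1.41 and by 1.23, and the list passed downward with median scaling (adjusted p = 0.0102 and 0.00287). Mesenchymal and cytoskeletal genes rose in 3 and fell in 3 of 13 (4 and 4 adjusted over the list alone) and rose in 3 and fell in 2 (3 and 3), with medians of -0.20 and -0.16 and means of 0.15 and 0.16 log2. The smooth muscle actin gene ACTA2 rose by 1.76 and 2.07 log2 and the transcription factor gene TWIST1 by 1.12 and 1.10, while the intermediate filament gene VIM fell by 1.52 and by 1.18. Inflammatory NF-kB genes rose in 3 and fell in 2 of 11 (4 and 2 adjusted over the list alone) and rose in 1 and fell in 0 (1 and 0). Aryl hydrocarbon receptor genes fell in 2 of 5 (2 adjusted over the list alone), then rose in 1 and fell in 1 (1 and 2), and passed downward in p53+/+ cells with median scaling (adjusted p = 0.0257). Iron handling genes fell in 1 of 7 (1 adjusted over the list alone), then rose in 1 and fell in 1 (1 and 1). Of other cell types, leukocyte markers rose in 1 and fell in 1 of 6 (1 and 1 adjusted over the list alone) and rose in 1 (1), while 3 fibroblast markers (1 and 0 lower) and 4 endothelial and erythroid markers (2 and 2 lower) were too few to test. Median, mean and test of a list differed in sign in p53-/- cells for the E2F, ATF4, NRF2, glycolysis, apoptosis, autophagy, proteasome and mesenchymal lists, and in p53+/+ cells for the NRF2, metallothionein, NF-kB and mesenchymal lists.

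A fall of YAP and TEAD targets with CCN1 (-0.60 log2 in p53-/- and -0.73 in p53+/+ cells) and CCN2 was a hypothesis, and the test argues against it. Without CCN1 and CCN2, 3 of 15 measured targets rose and 3 fell in p53-/- cells (4 and 4 adjusted over the list alone) and 2 rose and 2 fell in p53+/+ cells (3 and 4). The camera p was 0.811 and 0.877. The ectonucleotidase gene NT5E rose by 1.10 and 1.14 log2 and the phosphatase gene PTPN14 fell by 0.60 and by 0.54.

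Antigen presentation genes may have risen with the interferon response genes. Of 12 measured members that are not in the interferon list, 4 rose in p53-/- cells (4 adjusted over the list alone) and 2 in p53+/+ cells (4), and 0 fell, with a camera p of 0.00260 and 0.00565 over the 2 added lists, unadjusted. With an estimated correlation the p was 0.117 and 0.141. HLA-E rose by 1.46 and 1.19 log2 and B2M, the light chain of class I molecules, by 0.79 and 0.56. The peptidase gene ERAP2 rose by 1.88 in p53-/- cells and was at 0.19 in p53+/+ cells (adjusted p = 0.655). Its difference in response was -1.69 log2 and did not pass over all probes (adjusted p = 0.0884). In p53+/+ relative to p53-/- cells it was at 1.42 log2 before treatment (adjusted p = 0.0528) and at -0.27 after it (0.650). The genotypes thus differed mainly in the untreated arrays.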
